A study of Homo sapiens with 4 samples.

How the data were processed

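RNA was sequenced from organoids, self-organised clusters of cells grown from stem cells, at day 30 of culture. The organoids came from stable lines of H9, an established human embryonic stem cell line, that carried a lentiviral short hairpin RNA, which silences a gene by targeting its messenger RNA. The labels name a control hairpin, shCtrl, and a hairpin shCTCL, with 2 libraries each, and RNA was taken from 2 to 4 organoids of a group. The organ that the culture protocol leads to is not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and the columns of the count table were matched to the samples by hairpin name and replicate number. The labels do not say that the libraries of a group came from separate cultures. The p-values then measure only the spread between these samples, which can be technical.

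Per the labels, the authors mapped the reads to the hg19 genome with HISAT2 and measured transcripts with StringTie, and the deposited values are estimated counts per Ensembl gene that prepDE, a script of StringTie, derives from read coverage. Software versions, the annotation, the use of strand and the read length passed to prepDE are not given in the sources used here. The deposited estimated counts were whole numbers, so that no rounding was needed, and they were not scaled for library size. Among values from 2 to 30, 31.1% to 33.3% per library were multiples of 4, against 24.1% for evenly spread values. How many reads a deposited count stands for is thus unclear. Intervals and limits that start from counts take a deposited count as a read and cover at most counting error. The labels also name Ballgown, which tests transcript abundances, for the authors' own differential expression. It was not used here, because the table holds counts, which need a count model. Counting without strand cannot tell a gene from its antisense partner, and reads shared by overlapping or near-identical genes can be assigned to either, so such genes are given as uncertain.

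The table held 58233 genes. Of these, 55727 matched a name and hg19 coordinates in the reference tables (GENCODE release lifted to GRCh37), and 40935 had a gene symbol. Total counts were 130066018 in shCtrl 1, 98344838 in shCtrl 2, 94757992 in shCTCL 1 and 82669082 in shCTCL 2. At these totals, 3 counts in a library, taken as the detection limit, correspond to less than 0.1 CPM, the count scaled to library size used for all levels here. The libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 231 between the shCtrl libraries and 163 between the shCTCL libraries, and were kept as separate samples. With counts divided by 4, these values were 71.6 and 49.5.

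Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter, a robust quasi-likelihood fit with the group as the single term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Levels are TMM-normalised CPM, given as mean ± SD of 2 libraries, and fold changes run from shCtrl to shCTCL. A fold against a group at 0 counts is a lower bound that sets each library of that group at 3 deposited counts. The bound would be smaller if a deposited count stands for less than a read. With 2 libraries against 2, an exact permutation test of a single gene cannot reach the threshold, so single-gene p-values come from the model, which shares the spread across genes. Groups of 2 are too small to test a library as an outlier.

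Before the data were examined, 38 gene lists (cell types, pathways and quality measures, 486 entries) were fixed. Of the entries, 17 were matched by an older symbol, 3 (PECAM1, CCDC39 and HIST1H3B) were not matched and 2 repeated a gene under another symbol. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01, 2-sided), with adjustment over the lists. The value of a list is the median over its members of the difference in mean log2 CPM. The rule for named genes was also fixed beforehand. It takes the gene whose symbol or synonym is CTCL, and the 12 largest rises and the 12 largest falls among genes with a symbol that passed the test, reached a mean of 5 CPM in a group and did not overlap between groups. It further takes up to 3 members of each list that passed, or else the member with the smallest p, given as a value. Members named beyond this rule were chosen after their values were seen, and some genes that the rule takes are not described here.

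Alternatives fixed beforehand were DESeq2 size factors (DESeq2 1.42.0), scaling by library totals only, no filter, a filter of CPM above 1 in 2 libraries, the DESeq2 test, limma-voom, the replicate number as a block, each library left out in turn, rows with a symbol only and a minimum fold of 1.5. For the lists they were an estimated correlation, fry, a prior count of 0.5, the block, DESeq2 size factors and each library left out. Added after the data were seen were counts divided by 4, counts thinned to the smallest library total, and only protein-coding genes whose exons overlap no other gene. Overlaps were taken with bedtools 2.31.1, and near-identical genes with blastn 2.17.0 (95% identity over at least 50% of the longest transcript).

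The gene test was run on simulated counts for the same 22788 genes, with the means and library sizes of these samples. At each fold 50 genes were changed, drawn from those with a mean above 1 CPM, so recovery does not cover genes below this level. It recovered 8% of genes changed 2-fold, 60% of those changed 4-fold, 88% at 8-fold and 96% at 16-fold. Of its 144 calls, 18 were false. Changes of 2-fold were thus rarely detectable in this design, and a gene that did not pass is not shown to be unchanged. In 20 simulated lists of 12 random genes, drawn independently of each other, camera found the 1 shifted list and called none of the others. This does not check the preset correlation for lists whose genes vary together.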

Results

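Gene expression was measured by bulk RNA sequencing in 4 libraries from organoids of the human embryonic stem cell line H9 at day 30. In the labels, 2 libraries carried a control short hairpin RNA (shCtrl) and 2 the hairpin shCTCL. Total counts ranged from 82669082 in shCTCL 2 to 130066018 in shCtrl 1, and between 26849 and 31216 genes had a count above 0. Levels below are mean ± SD in CPM over the 2 libraries of a group, and adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for lists.

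The gene that the hairpin label points to was examined first. In the gene tables used here, CTCL was a synonym of TSPYL2 alone (ENSG00000184205, hg19 chromosome X, 53111549 to 53117722, protein coding), a gene of the nucleosome assembly protein family. The labels do not say whether TSPYL2 is the target of the hairpin. TSPYL2 stood at 31.3 and 32.3 CPM in the shCtrl libraries and at 35.3 and 36.7 CPM in the libraries labelled shCTCL. Its log2 fold change was 0.18 (SE 0.20, 95% interval -0.32 to 0.67, edgeR adjusted p = 0.677). TSPYL2 was thus not lower in the libraries labelled shCTCL, and it does not check the labels. Every direction given below is between the libraries as labelled.

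The comparison addresses how gene expression at day 30 differed between organoids with the shCTCL hairpin and organoids with the control hairpin. Genes of the telencephalon, of cortical and ventral forebrain neurons and of neurons in general were higher in the libraries labelled shCTCL as lists. Lists of WNT and BMP targets, choroid plexus, midbrain and hindbrain, mesenchyme, muscle, cell division and ribosomal proteins were lower. These calls held with a preset correlation between genes, and none held with an estimated one (adjusted p = 0.687 to 0.787 with an estimated correlation over the 18 lists called). An estimate from 2 libraries per group is weak, and the lowest unadjusted p of any list in that camera test was 0.0525. Whether that test could find a list that differs was not tried on simulated lists, so it does not show that the lists are unchanged. Fry, an alternative list test, also called 0 lists (lowest fry adjusted p = 0.0668). The calls thus rest on the preset correlation. TBR1, a transcription factor of early-born cortical neurons, averaged 0.261 ± 0.0894 CPM in shCtrl and 442 ± 3.78 CPM in the libraries labelled shCTCL (SD, n = 2 each). TFAP2B, which codes for the transcription factor AP-2 beta, fell from 88.2 ± 27.4 to 2.04 ± 0.0922 CPM. Among 22788 genes tested with edgeR, 246 were higher and 149 were lower in the libraries labelled shCTCL, and 221 and 135 of these were protein coding. At an unadjusted p under 0.05 the numbers were 2110 and 2303. The groups did not overlap for 53.7% of the tested genes, against 33.3% by chance. The first principal component held 61.2% of the variance and separated the groups. Across the 22788 tested genes, which are not independent replicates, the Pearson correlation of log2(TMM-normalised CPM + 1) was 0.980 between the shCtrl libraries and 0.984 between the shCTCL libraries, and 0.936 to 0.971 between groups. The total of 395 genes became 651 without shCtrl 1, 233 without shCtrl 2, 21 without shCTCL 1 and 221 without shCTCL 2. It became 1683 without a filter, 610 with the stricter filter, 2551 in the DESeq2 test, 208 with a minimum fold of 1.5 and 718 with counts divided by 4.

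Among genes with a symbol, the 12 largest rises by fitted log2 fold change were mostly transcription factor genes of the forebrain that were close to undetected in shCtrl. EMX2 (ENSG00000170370, hg19 chromosome 10, 119301956 to 119309057), a homeobox gene of the dorsal telencephalon, rose from 0.104 ± 0.104 to 255 ± 117 CPM (log2 fold change 11.32, SE 0.83, adjusted p = 0.00832). TBR1 (ENSG00000136535, chromosome 2, 162272808 to 162282381) rose by 10.70 on the log2 scale (SE 0.40, adjusted p = 0.0022), from 62 counts in the shCtrl libraries together to 77521 in those labelled shCTCL. The zinc finger genes FEZF1 (ENSG00000128610, chromosome 7, 121941357 to 121950745) and FEZF2 (ENSG00000153266, chromosome 3, 62355356 to 62359999) act in forebrain patterning. FEZF1 rose from 0.456 ± 0.0549 to 337 ± 92.5 CPM and FEZF2 from 0.306 ± 0.265 to 157 ± 87.5 CPM (adjusted p = 0.0022 and 0.0151). EOMES, a marker of intermediate progenitors of the cortex, rose from 0.0989 ± 0.14 to 39.3 ± 5.75 CPM. DMRT3 rose from 0.452 ± 0.214 to 63.1 ± 2.48 CPM, and SIX3, an anterior forebrain and eye field gene, from 0.345 ± 0.124 to 45.6 ± 11.7 CPM. The rises of EMX2OS, FEZF1-AS1 and LHX5-AS1 (log2 fold changes 9.32, 8.48 and 7.05) are uncertain, since each overlaps its partner gene and the use of strand is not given in the sources used here. The same holds in reverse for EMX2, FEZF1, SIX3 and TBR1, which overlap other genes. Their sums with the overlapping genes still had log2 ratios of 10.33, 8.96, 6.91 and 7.47, in this order. A rise thus remained in each sum, and the share of each gene in it is uncertain. RIMBP3B had 0 counts in shCtrl and averaged 7.54 ± 1.84 CPM in the libraries labelled shCTCL, at least 285-fold higher. RIMBP3B shares near-identical sequence with RIMBP3 and RIMBP3C, and the log2 ratio of the sum over these genes was 2.43. Without shCTCL 1, 6 of the 12 lost their call (among them RIMBP3B, EMX2, FEZF2, EOMES and FEZF1-AS1, adjusted p up to 0.174), and EOMES also did without shCTCL 2. Without the filter, FEZF2 and EOMES did not pass.

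**Figure D1:**
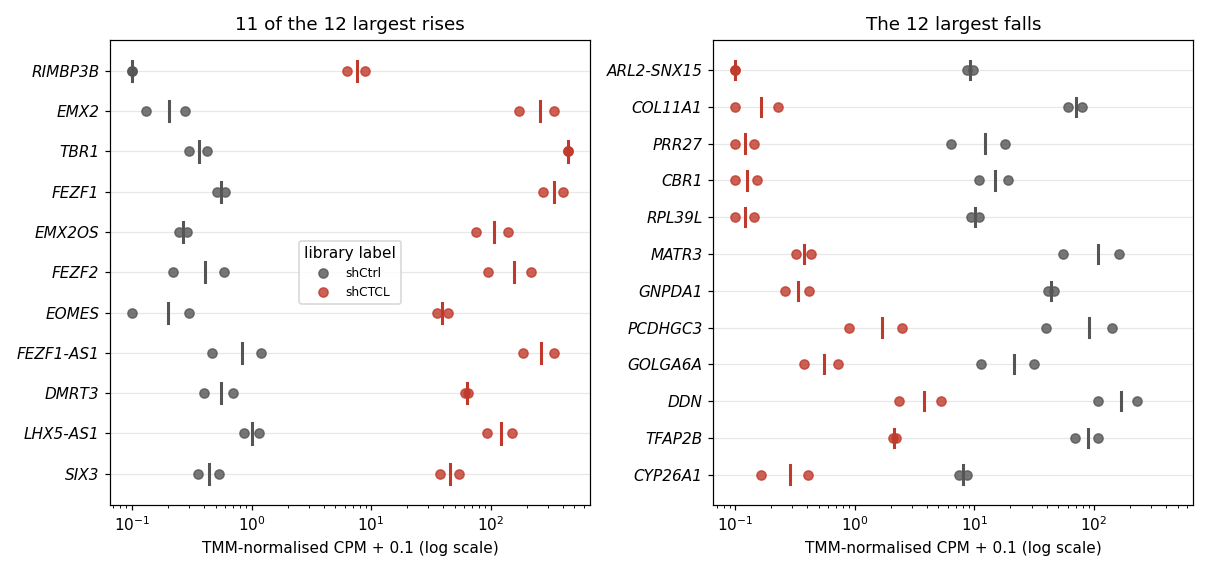
TMM-normalised CPM plus 0.1, on a log scale, of 11 of the 12 largest rises (left) and of the 12 largest falls (right). Each point is a library, coloured by its label (shCtrl grey, shCTCL red, 2 each), and each vertical bar is a group mean. RIMBP3B was at 0 in both shCtrl libraries and ARL2-SNX15 at 0 in both libraries labelled shCTCL, and TBR1 averaged 0.261 against 442 CPM.

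Of 10 tested genes of the telencephalic identity list, 4 rose, 1 fell and 5 did not pass, with 5 higher and 1 lower when adjusted over the list alone. The list was higher, with a median of 1.87 on the log2 scale (camera adjusted p = 3.81e-04, and adjusted p = 0.687 with an estimated correlation). Besides EMX2, NR2E1, a nuclear receptor gene of neural stem cells, rose from 12.5 ± 2.35 to 111 ± 21.1 CPM, and EMX1 rose from 0.195 ± 0.0462 to 2.84 ± 0.871 CPM. OTX1, a homeobox gene of forebrain and midbrain, fell from 333.5 ± 29.96 to 64.6 ± 17.2 CPM (adjusted p = 0.0237). The glutamatergic cortical neuron list was higher (12 tested, median 1.82, camera adjusted p = 0.00104, and adjusted p = 0.687 with an estimated correlation). In it 5 genes rose, or 6 when adjusted over the list alone: TBR1, FEZF2, BHLHE22, NEUROD2 and NEUROD1, a neurogenic factor that went from 4.68 ± 0.767 to 31.8 ± 10.3 CPM. SLC17A7, a gene of mature cortical projection neurons, was at 4.06 CPM in shCtrl and at 3.23 CPM in the libraries labelled shCTCL and did not pass. The list of ventral forebrain and GABAergic neurons was also higher (13 tested, median 2.75, camera adjusted p = 4.88e-05, and adjusted p = 0.687 with an estimated correlation). Genes that rose in it included SIX3, GAD1, GAD2 and SLC32A1, the vesicular transporter of GABA. SLC32A1 went from 1.75 ± 1.29 to 70.7 ± 27.6 CPM. When adjusted over the list alone, 8 of its genes were higher and 2 lower. Without shCTCL 1, TBR1 and SIX3 kept their calls and the other genes called in this paragraph lost them. BHLHE22, NEUROD2, GAD2 and SLC32A1 also lost theirs without shCTCL 2 and NEUROD2 and GAD1 without shCtrl 2 (adjusted p up to 0.182), and EMX1 did with any library left out (adjusted p = 0.0576 to 0.11).

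In the Cajal-Retzius and preplate list (8 tested), LHX5 and LHX1 rose and no gene fell. When adjusted over the list alone, 3 were higher and 1 lower. LHX5, a LIM homeobox gene, rose from 6.59 ± 2.63 to 804 ± 272 CPM (log2 fold change 6.93, SE 0.48, adjusted p = 0.00749). It overlaps LHX5-AS1, and the sum of both had a log2 ratio of 6.94. RELN, the reelin gene of Cajal-Retzius cells, was at 7.17 ± 0.809 and 17.9 ± 2.05 CPM and did not pass (adjusted p = 0.0755). The list had a median of 0.74 (camera adjusted p = 0.0191, 0.0992 without shCtrl 1, and adjusted p = 0.687 with an estimated correlation). In the intermediate progenitor list (9 tested), the proneural genes NEUROG1 and NEUROG2 rose together with EOMES, and 5 genes were higher when adjusted over the list alone. NEUROG2 went from 28.3 ± 7.56 to 303 ± 93.9 CPM. Its median was 0.74 (camera adjusted p = 0.00104, and adjusted p = 0.687 with an estimated correlation). Of 15 pan-neuronal genes 4 rose (MAPT, MYT1L, ELAVL4 and INA) and 11 did not pass, whereas 13 were higher when adjusted over the list alone. MAPT, which codes for the protein tau, rose from 55.9 ± 2.32 to 218 ± 32.1 CPM. This list had a median of 1.52 (camera adjusted p = 6.12e-08, and adjusted p = 0.701 with an estimated correlation). Of 15 synapse genes 4 rose (among them GRIK2, GRIA2 and SYN1), or 12 when adjusted over the list alone, with a median of 1.18 (camera adjusted p = 4.29e-07, and adjusted p = 0.687 with an estimated correlation). GRIK2, a kainate receptor subunit gene, went from 3.34 ± 0.0787 to 26.7 ± 0.387 CPM. Of the 26 members named by the rule that passed, over all lists, 22 lost their call without shCTCL 1, 7 without shCtrl 2, 6 without shCTCL 2 and 1 without shCtrl 1, with adjusted p up to 0.19. Of these members TBR1, SIX3, LHX5 and FAM107A passed in each of these fits and HEY2, a Notch target, in none. Over these fits the log2 fold change ran from 2.966 to 3.001 for GRIK2, from 1.81 to 2.06 for MAPT and from 3.13 to 4.39 for GRIA2. That of EOMES ran from 7.62 to 14.95, the latter without shCtrl 2, against 8.72 with all libraries. EOMES had 0 counts in shCtrl 1, so the size of the value without shCtrl 2 is not an estimate. INA and SYN1, named beyond the rule, passed in none of these fits (adjusted p = 0.0521 to 0.21).

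**Figure D2:**
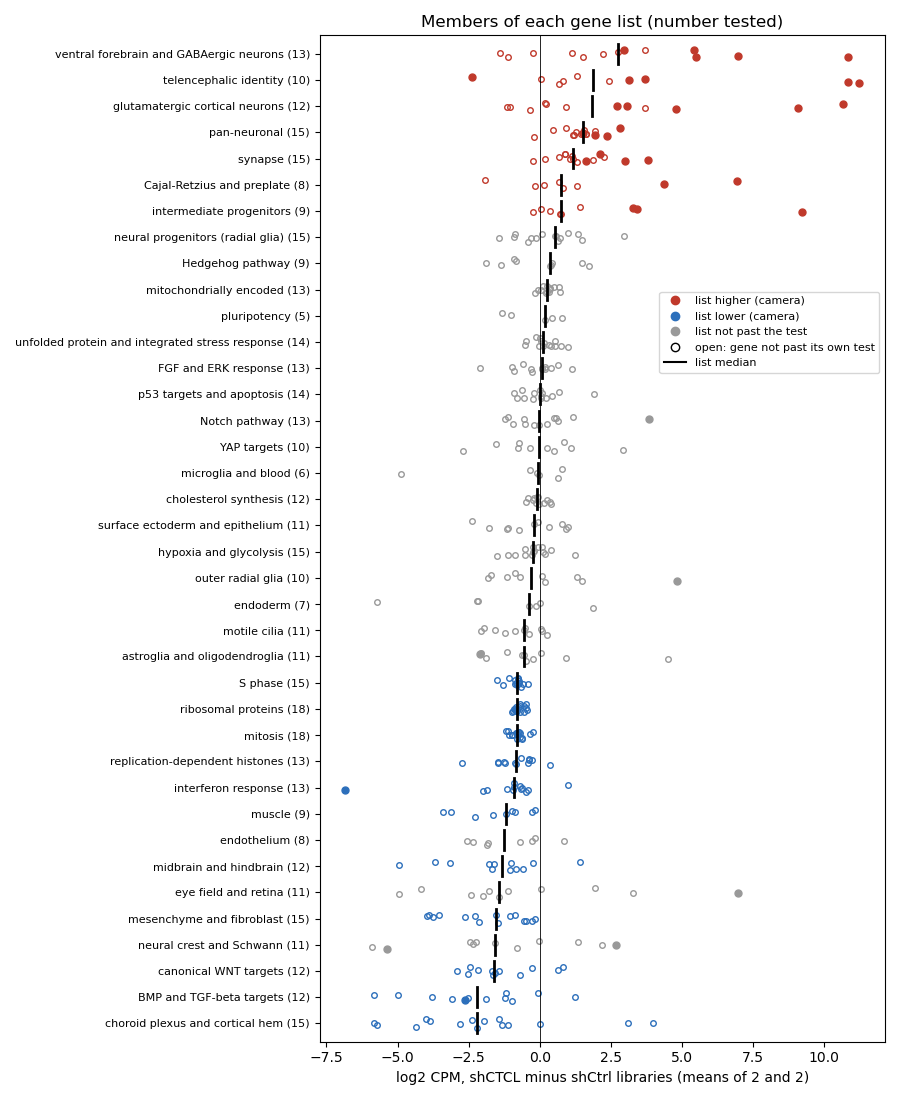
Difference in mean log2 CPM (shCTCL minus shCtrl, 2 libraries each) of each tested member of the 38 gene lists, with the number tested in parentheses. Each circle is a gene, filled where it passed its own edgeR test, each black bar is the list median, and colour marks lists called higher (red) or lower (blue) by camera. The medians run from -2.21 for choroid plexus and cortical hem to 2.75 for ventral forebrain and GABAergic neurons.

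Among genes with a symbol, the 12 largest falls included genes that dropped to a few counts in the libraries labelled shCTCL. COL11A1 (ENSG00000060718, hg19 chromosome 1, 103342023 to 103574428), which codes for a chain of the fibrillar collagen XI, went from 69.8 ± 12.9 to 0.0641 ± 0.0907 CPM, or from 16363 counts to 12 (log2 fold change -9.99, SE 0.87, adjusted p = 0.0113). Without shCTCL 1 the log2 fold change was -15.83. This was fitted against 0 counts in shCTCL 2, so its size is not an estimate. GNPDA1 (ENSG00000113552, chromosome 5, 141371314 to 141392606), a glucosamine-6-phosphate deaminase gene, fell from 43.7 ± 3.96 to 0.235 ± 0.107 CPM (log2 fold change -7.52, SE 0.42, adjusted p = 0.00406). CBR1, a carbonyl reductase gene, went from 14.8 ± 5.58 to 0.0267 ± 0.0378 CPM. RPL39L, a paralog of a ribosomal protein gene, went from 10.1 ± 1.05 to 0.0214 ± 0.0302 CPM, and PRR27 from 12.05 ± 8.14 to 0.0214 ± 0.0302 CPM. TFAP2B (ENSG00000008196, chromosome 6, 50786436 to 50815332) had a log2 fold change of -5.43 (SE 0.33, adjusted p = 0.00406). DDN, which codes for the postsynaptic protein dendrin, fell from 168 ± 86.0 to 3.69 ± 2.03 CPM. CYP26A1, a gene of retinoic acid breakdown, fell from 7.91 ± 0.906 to 0.185 ± 0.171 CPM. Of the 12, 6 are uncertain because their counts can be shared with other genes. ARL2-SNX15, a readthrough gene of ARL2 and SNX15, had 0 counts in the libraries labelled shCTCL and was at least 264-fold lower, but its sum with both genes had a log2 ratio of -0.17. The MATR3 gene with the identifier ENSG00000280987 and PCDHGC3 also overlap other genes, and their sums had log2 ratios of -0.19 and 0.64. GOLGA6A has near-identical paralogs, and its sum with them had a log2 ratio of -5.26. CBR1 and DDN overlap antisense genes and are uncertain too, though their sums with the overlapping genes still had log2 ratios of -8.36 and -5.18. The log2 fold change of CBR1 moved from -8.98 to -13.59 without shCTCL 1. CBR1 had 0 counts in shCTCL 2, so the size of the latter value is not an estimate. Without shCTCL 1, 8 of the 12 lost their call (PRR27, CBR1, MATR3, PCDHGC3, GOLGA6A, DDN, TFAP2B and CYP26A1, adjusted p up to 0.211), and PRR27, MATR3, PCDHGC3 and GOLGA6A also did without shCTCL 2. PRR27 and GOLGA6A did not pass with limma-voom, COL11A1 and PCDHGC3 without the filter, and PCDHGC3 with a minimum fold of 1.5.

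Targets of secreted signals were lower as lists in the libraries labelled shCTCL. The list of BMP and TGF-beta targets (12 tested) had a median of -2.20 (camera adjusted p = 0.00104, and adjusted p = 0.775 with an estimated correlation), and of -1.38 without shCTCL 1. Its mean log2 CPM was 2.354 in shCTCL 1 and 4.051 in shCTCL 2. ID2, an inhibitor of basic helix-loop-helix factors, fell from 48.7 ± 11.3 to 7.98 ± 3.01 CPM (adjusted p = 0.0304, and not past without shCTCL 1, where it was 0.132), and 11 genes did not pass. When adjusted over the list alone, 7 were lower and 1 was higher. ID4 was the member on the higher side, at 346 ± 94.6 and 800 ± 64.8 CPM. The list of canonical WNT targets (12 tested) had a median of -1.60 (camera adjusted p = 0.00104, and adjusted p = 0.775 with an estimated correlation). None of its genes passed over all genes, and 7 were lower when adjusted over the list alone. AXIN2, a feedback inhibitor of WNT signalling, was at 551 ± 108 CPM in shCtrl and at 107 ± 56.1 CPM in the libraries labelled shCTCL (adjusted p = 0.0544). The choroid plexus and cortical hem list (15 tested, median -2.21, camera adjusted p = 0.00478, and adjusted p = 0.787 with an estimated correlation) also had no member past over all genes, and 5 lower and 2 higher when adjusted over the list alone. WNT2B was at 67.1 ± 32.1 and 12.5 ± 4.46 CPM (adjusted p = 0.0547). The libraries of each group stood apart in this list. Its mean log2 CPM was 3.462 in shCtrl 1, 5.292 in shCtrl 2, 1.235 in shCTCL 1 and 3.535 in shCTCL 2, so that the groups overlapped. TTR, an abundant choroid plexus transcript, was at 308 CPM in shCtrl 2, 51.5 CPM in shCtrl 1, 0.321 CPM in shCTCL 1 and 16.6 CPM in shCTCL 2. FOXJ1, a regulator of motile cilia, was at 874 CPM in shCtrl 2 and between 127 and 281 CPM in the others. The choroid plexus list did not pass without shCtrl 2 or without shCTCL 1 (adjusted p = 0.0758 and 0.18), and its median was -0.90 without shCtrl 2 and -3.28 without shCtrl 1.

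The midbrain and hindbrain list (12 tested, median -1.33, camera adjusted p = 0.0238, and adjusted p = 0.775 with an estimated correlation) had no member past over all genes and 1 lower when adjusted over the list alone. WNT1, a signal of the midbrain and hindbrain boundary and the roof plate, was at 276 ± 26.0 CPM in shCtrl and at 13.3 ± 13.9 CPM in the libraries labelled shCTCL (adjusted p = 0.0792). This list was lost without shCtrl 1 or without shCTCL 1 (adjusted p up to 0.47). Its median was -0.55 without shCtrl 1, -3.05 without shCtrl 2 and -2.21 without shCTCL 2. The mesenchyme and fibroblast list (15 tested, median -1.55, camera adjusted p = 7.94e-05, and adjusted p = 0.744 with an estimated correlation) had 6 genes lower when adjusted over the list alone and none past over all genes, and its median was -2.51 without shCTCL 2. COL1A2, a chain of collagen I, was at 353 ± 150 and 59.1 ± 30.8 CPM (adjusted p = 0.0601). The muscle list (9 tested, median -1.20, camera adjusted p = 0.00104, and adjusted p = 0.687 with an estimated correlation) likewise had 3 lower over the list alone and none over all genes, and its median was -0.76 without shCtrl 2. Of its genes TNNT1, a troponin gene, was at 22.1 ± 8.26 and 4.71 ± 2.60 CPM, and others, such as MYOG, stayed below 1 CPM in every library.

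Lists of cell division were lower with no single member past the test. The S phase list (15 tested) had a median of -0.78 (camera adjusted p = 6.36e-04, and adjusted p = 0.775 with an estimated correlation) and the mitosis list (18 tested) one of -0.79 (camera adjusted p = 0.00104, and adjusted p = 0.775 with an estimated correlation). All members of both lists had a negative log2 fold change, and none passed when adjusted over the list alone. TYMS, the thymidylate synthase gene, was at 81.0 ± 9.22 and 30.2 ± 13.1 CPM, and CCNB1, the cyclin B1 gene, at 79.9 ± 14.7 and 38.5 ± 16.8 CPM. The S phase list did not pass without shCTCL 1 (adjusted p = 0.0719), and the mitosis list neither without shCTCL 1 nor without shCtrl 1 (adjusted p up to 0.137). The S phase median was -0.37 without shCTCL 1 and -1.33 without shCTCL 2. The mitosis median was -0.40 without shCTCL 1, -1.31 without shCTCL 2, -0.46 without shCtrl 1 and -1.20 without shCtrl 2. Mean log2 CPM of the mitosis list was 6.456 in shCtrl 1, 5.76 in shCtrl 2, 4.925 in shCTCL 1 and 5.707 in shCTCL 2. All 18 ribosomal protein genes had a negative log2 fold change (median -0.79, camera adjusted p = 2.04e-05, and adjusted p = 0.775 with an estimated correlation). None passed over all genes and 9 were lower when adjusted over the list alone. RPS6 was at 1075 ± 71.0 and 556 ± 107 CPM. The replication-dependent histone list (13 tested, median -0.85, camera adjusted p = 0.00311, and adjusted p = 0.687 with an estimated correlation) had no gene past either way, and H2BC12 was at 13.5 ± 0.0926 and 5.01 ± 1.83 CPM. It was just lost without shCtrl 1 (adjusted p = 0.0503). In the interferon response list (13 tested, median -0.89, camera adjusted p = 0.00311, and adjusted p = 0.775 with an estimated correlation), OAS3 was the gene that passed, over all genes and over the list alone. It had 510 counts over the shCtrl libraries (2.26 ± 0.541 CPM) and 0 in those labelled shCTCL, at least 65.6-fold lower (adjusted p = 0.0219, and 0.0833 without shCTCL 1). The interferon list was lost without shCtrl 2 or without shCTCL 1 (adjusted p up to 0.117), and its median was -1.44 without shCTCL 2 and -1.35 without shCtrl 1.

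The other 20 lists did not pass, with camera adjusted p from 0.0723 for neural crest and Schwann to 0.978. The median was 0.53 for neural progenitors, -0.31 for outer radial glia, 0.20 for pluripotency, -1.43 for eye field and retina, -1.58 for neural crest and Schwann and -0.56 for astroglia and oligodendroglia. It was -1.25 for endothelium, -0.20 for surface ectoderm, -0.36 for endoderm, -0.06 for microglia and blood, 0.01 for p53 targets and 0.13 for the unfolded protein and integrated stress response. The remaining medians were -0.24 for hypoxia and glycolysis, -0.02 for Notch, 0.38 for Hedgehog, -0.04 for YAP targets, 0.07 for FGF and ERK response, -0.09 for cholesterol synthesis, -0.55 for motile cilia and 0.27 for mitochondrially encoded genes. For pluripotency, outer radial glia, microglia and blood, p53 targets, Notch, Hedgehog and FGF and ERK response, the median, the mean and the direction of the test differed in sign. Within these lists, FAM107A, a marker of outer radial glia, rose from 6.60 ± 1.54 to 188 ± 27.3 CPM (adjusted p = 0.00406). Of the neural crest list, TFAP2B fell and ETS1 rose, from 2.997 ± 0.839 to 19.1 ± 4.88 CPM. CSPG4, a proteoglycan gene of oligodendrocyte precursors and pericytes, fell from 15.7 ± 2.88 to 3.62 ± 0.551 CPM. HEY2 rose from 0.588 ± 0.0351 to 9.88 ± 6.77 CPM (adjusted p = 0.0383, but 0.0566 to 0.086 with any of the 4 libraries left out). ETS1 and CSPG4 lost their calls without shCtrl 2, shCTCL 1 or shCTCL 2 (adjusted p up to 0.154 and 0.19), and TFAP2B lost its call without shCTCL 1 (0.0608). SIX3 was the eye field gene that rose. PAX6, a transcription factor of forebrain progenitors, was at 32.3 ± 20.3 and 229 ± 60.2 CPM and did not pass (adjusted p = 0.0533). When adjusted over the list alone, genes passed in some of the 20 lists: 2 higher and 1 lower in neural progenitors, 2 and 2 in outer radial glia, 3 and 6 in eye field, 2 and 5 in neural crest, and 2 and 4 in YAP targets. In Hedgehog these were 1 and 2, in hypoxia, Notch and FGF 1 and 1 each, 1 higher in p53 targets, and 1 lower each in astroglia and endothelium. Without shCtrl 1, the neural progenitor, endothelium, motile cilia and mitochondrial lists passed (lowest adjusted p 2.88e-04, for motile cilia). The neural crest list passed without shCtrl 2 or without shCTCL 1 (0.0344 and 0.0367), and the unfolded protein list without shCTCL 1 (0.0122).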

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

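Dividing the counts by 4, thinning to the smallest total and keeping only protein-coding genes that overlap no other gene were chosen after the data were seen. None of the 395 genes called changed sign under any setting that gave it a value. Of these genes 391 passed with DESeq2 size factors, 363 with library totals only, 387 without a filter, 395 in the DESeq2 test, 357 with limma-voom and 385 after thinning. Without shCtrl 1, shCtrl 2, shCTCL 1 and shCTCL 2 in turn, 310, 176, 17 and 162 of them passed. Without a filter, 852 genes were higher and 831 lower among 36988 tested. The DESeq2 test gave 1220 higher and 1331 lower, a minimum fold of 1.5 gave 138 and 70, and counts divided by 4 gave 436 and 282. The filter of CPM above 1 in 2 libraries gave 367 higher and 243 lower. Leaving out a library gave 13 to 302 higher and 8 to 349 lower, with the lowest counts without shCTCL 1 and the highest without shCtrl 1. These fits leave a group with a single library, which is assumed to vary like the other group. With the replicate number as a block, 555 genes were higher and 506 lower, and 390 of the 395 passed. The labels do not say that the numbers pair libraries. The correlation of deviations between same-numbered libraries was 0.257, with 2 pairs of libraries. The second principal component held 22.3% of the variance. It was negative in shCtrl 1 and shCTCL 1 and positive in shCtrl 2 and shCTCL 2. A difference shared by same-numbered libraries thus stays open, and 2 pairs are too few to decide it. The cause of the shifts in the numbers of genes called was not tested. With an estimated correlation 0 lists were higher and 0 lower, and none had an unadjusted p under 0.05. Whether that test could pass a list that differs was not tried on simulated lists, so it does not show that the lists are unchanged. With fry, which tests whether a list moves on balance in a single direction, the counts were also 0 and 0 after adjustment, and 8 and 3 at an unadjusted p under 0.05. The preset correlation gave 7 and 11, and leaving out a library 7 to 8 higher and 7 to 11 lower. A change of 2-fold was recovered for 8% of the genes so changed in the simulation, all with a mean above 1 CPM, which limits what 2 libraries per group can show.

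Over the named genes, 1311 values under alternatives kept their direction and their side of the threshold, 126 fell short of it, 82 newly passed and 3 reversed. For the lists these numbers were 259, 47, 8 and 28. No gene or list that was called reversed. With a library left out, the log2 fold changes that reversed ran from -2.69 to 0.0674 for LIN28A, -3.39 to 0.199 for DNAI2 and -2.09 to 0.571 for FOXJ1. The direction of the test turned for lists whose medians ran from -0.621 to 0.419 for pluripotency, -0.0295 to 0.700 for neural progenitors, -0.760 to 0.356 for outer radial glia, -1.22 to -0.0602 for astroglia, -0.981 to 0.0958 for surface ectoderm and -0.497 to 0.340 for microglia and blood. They ran from -0.299 to 0.0728 for p53 targets, -0.220 to 0.449 for the unfolded protein response, -0.504 to 0.0462 for hypoxia, -0.237 to 0.231 for Notch and -0.443 to 0.275 for Hedgehog. The others were YAP targets (-0.326 to 0.0525), FGF and ERK response (-0.289 to 0.0610), cholesterol synthesis (-0.263 to 0.158) and motile cilia (-1.70 to 0.520). Under fry the direction turned for outer radial glia (median -0.308), eye field and retina (-1.43) and p53 targets (0.0145), and under the block for microglia and blood (-0.0553). The cause was not tested.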

Other observations

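The tests of a larger share of neurons, of exchanged labels of both groups, of a gained or lost chromosome and of counts assigned to overlapping or near-identical genes were chosen after the result was seen, as were the 12 gene families described here and their named members.

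Families of patterning genes are described by values only, since they were picked from genes already seen to differ and a test of them on the same data would carry no weight. Of 5 tested genes of the DMRT family of transcription factors (median 4.94 on the log2 scale), DMRT3, DMRTA1 and DMRTA2 rose, the last from 5.03 ± 1.85 to 306 ± 95.1 CPM. Of 6 Iroquois homeobox genes (median -3.19), IRX1 fell from 316 ± 40.9 to 18.2 ± 0.728 CPM and IRX2 from 177 ± 71.6 to 17.7 ± 1.11 CPM. Of 12 genes of retinoic acid metabolism (median -1.32), CYP26A1 and CYP26C1, genes of retinoic acid breakdown, fell. Of 17 WNT ligands (median -2.22), WNT3 fell from 133 ± 12.4 to 12.2 ± 7.50 CPM and WNT7B rose from 38.4 ± 28.2 to 759 ± 60.7 CPM. FZD10, a WNT receptor gene, fell from 556 ± 255 to 20.9 ± 13.5 CPM, and the median over 10 frizzled genes was -0.58. None of 14 HOX genes (median -1.17) or 8 BMP ligands (median -0.97) passed its own test. LHX1 and LHX5 rose among 11 LIM homeobox genes (median 0.04). Without shCTCL 1, DMRT3, DMRTA2 and LHX5 kept their calls and the other genes called in this paragraph lost them (adjusted p up to 0.157). IRX2, CYP26C1 and WNT7B also lost theirs without shCTCL 2, and WNT3 without either shCtrl library.

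Receptor genes of neurons are given in the same way. Of 16 subunits of AMPA, kainate and NMDA receptors (median 1.12), GRIK2 and GRIA2 rose, and GRIK4 fell from 19.6 ± 7.09 to 3.85 ± 0.338 CPM. Of 10 GABA-A receptor subunits (median 0.92), those that rose included GABRA3, from 9.06 ± 3.09 to 42.8 ± 6.02 CPM, and GABRB2. Of 22 clustered gamma protocadherins (median 1.20), PCDHGA10 and PCDHGB7 rose and PCDHGC3 fell, but these genes share exons and their counts are uncertain. Of 22 ephrins and Eph receptors (median 0.10), EPHA5 rose and EPHA8 fell. Without shCTCL 1, each gene called in this paragraph lost its call (adjusted p up to 0.211). Calls were also lost without shCtrl 2 for GRIA2, GRIK4, GABRA3, GABRB2, PCDHGA10, EPHA5 and EPHA8, without shCTCL 2 for GRIK4, GABRA3, PCDHGA10, PCDHGC3 and EPHA8, and without shCtrl 1 for GABRB2 and EPHA5.

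Of 34 tested members of the telencephalic, glutamatergic and ventral forebrain lists, whose calls were lost with an estimated correlation (adjusted p = 0.687 for each list), 13 rose and OTX1 fell. The 13 all (100%) passed after thinning to the smallest total. They were chosen for passing in the same counts and could hardly lose their calls, so no conclusion on the difference in total counts is drawn from this. Exchanging 1 library of each group gave 0 genes with edgeR in either of the other 2 splits (404 and 129 at an unadjusted p under 0.05; 23 and 19 with the DESeq2 test and 0 with limma-voom), against 395 as labelled, and 3 splits in all are too few for a share under 0.05. The largest distance of a chromosome's median from that of all others was 0.0876, on chromosome 7, where an extra copy would give 0.585. This argues against a whole chromosome gained or lost in all cells of a group. A change of part of a chromosome, or in part of the cells, could leave these medians close together and stays open. A larger share of neurons stays open: the 13 members that rose had a median log2 fold change of 5.34 but were chosen for passing, and over all 34 tested members the median was 2.33, between the pan-neuronal median of 1.54 and the highest pan-neuronal value of 2.85. The hairpin, a difference between the stable lines and a difference between cultures stay open too, and a difference in regional identity of the organoids may be put forward only as a hypothesis, since none of these was tested.

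Among genes past the test, 38 reached 5 CPM in a group and differed more than 32-fold between groups. Of the 20 with an overlapping gene, the sum with it differed by less than 2-fold for 15%, and of the 5 with a near-identical gene for 40%, so that counts assigned to another gene stay open as a cause for part of the set. For PCDHGC3, UBBP4, ARL2-SNX15 and the MATR3 gene ENSG00000280987 the sums differed by at most 0.643 on the log2 scale, and a candidate explanation is that reads were assigned to another gene. For the other 18 of the 22 with either kind of partner the sums differed by at least 2.41, and 16 genes, among them GNPDA1, RPL39L, COL11A1 and PRR27, had no partner to sum. What made these differ stays open, as no biological explanation was tested.

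TSPYL2 was not lower in the libraries labelled shCTCL. Its 95% interval of -0.32 to 0.673 on the log2 scale excludes a 2-fold change either way, so it says nothing on whether the labels of both groups were exchanged. Reads of near-identical genes counted in TSPYL2 are argued against by 0 other genes with a near-identical transcript. Whether the hairpin targets another gene, or targets TSPYL2 without a 2-fold loss of its messenger RNA at day 30, stays open. The target of the hairpin was not tested.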
